A study of Pseudomonas putida KT2440 with 12 samples.

How the data were processed

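The 12 arrays hold total RNA of Pseudomonas putida KT2440 from plates with and without Arabidopsis thaliana at 48 h and 120 h, with 3 biological replicates (A, B and C) in each of the 4 groups, per the labels. Groups and replicate letters were taken from the sample titles. Per the labels' protocols, cells were scraped from the plates into an RNA stabiliser, DNase-treated total RNA was turned into double-stranded cDNA, and the array maker labelled it with Cy3 in 1 colour. Both strands of the cDNA were labelled, so transcripts of opposite strands cannot be told apart.

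The deposited probe files give the raw intensity of 385200 spots per array, per the file headers and the values, with 18 perfect-match probes for each of 5350 genes in each of 4 blocks. The mismatch column is 0 throughout, and the files used list no random or control probes and no detection calls. The deposited calls files give, per the file headers, a mean intensity per gene and block after the authors' software dropped outlying probes. The deposited series table gives a positive linear intensity per gene. Its column medians were 152.9, 155.9 and 153.6 for controls at 48 h (A, B, C), 152.7, 154.6 and 154.6 for plants at 48 h, 154.1, 155.8 and 155.2 for controls at 120 h, and 153.5, 155.6 and 154.6 for plants at 120 h. Its columns followed the raw values of the same arrays with a Spearman correlation across genes of 0.950 to 0.983, so that its direction is that of intensity. How the authors centred and normalized it is not given in the sources used here and stays unknown, and it served as an alternative only. Array reading software and settings are not given in the sources used here.

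Gene values were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50, fitted on all spots of an array, and arrays were quantile-normalized over spots. The 4 spots of a probe were averaged, and the 18 probes of a gene were combined by median polish on the log2 scale with at most 30 iterations. At most 29 spots on an array were saturated, and they were kept. Because no control probes were listed, background was taken as the 10th percentile of genes (log2 level 7.70), and genes whose dimmer group lay near it have understated folds. No gene was left out of the fit.

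One mean per group was fitted over all 12 arrays with lmFit, contrasts and eBayes (8 residual and 4.26 prior degrees of freedom), so that groups share an estimate of the spread. The contrasts were plant minus control at each time, 120 h minus 48 h without and with plants, and the difference of the plant effects. Tests were two-sided, with Benjamini-Hochberg adjustment over 5350 genes and a threshold of 0.05. Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, with the correlation estimated per list as an alternative, and with fry, which asks whether a list's genes move one way without comparing them with other genes. Adjustment was over the 30 lists with at least 5 genes, of 32 defined. With an estimated correlation 1 of the 4 lists called at 48 h held, the ATP synthase list, and none of the lists called in the other comparisons. List tests for the time comparisons and the difference of plant effects were added to the design.

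Groups, tests, the alternatives except those named as added, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each plant comparison, the 10 genes with the largest change in each direction past the threshold whose 3 plant arrays all lay on one side of the 3 control arrays and whose mean was above background in a group. For each time comparison and for the difference of plant effects it took 5 in each direction, without the condition on overlap for the latter. For each list it took up to 4 called members with the largest change, or up to 2 with the smallest p given as values. Genes named outside this rule are those of the cluster PP3775 to PP3788, PP2698, members called against their list's direction, GroEL, DnaK, the members of the lists too short to test (PP4216 and the VgrG genes), and the runs of neighbouring genes.

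The lists were built by matching name patterns to the product text and symbols in the array files: flagellum, chemotaxis, pyoverdine, siderophore receptors, aromatic catabolism, glucose, TCA cycle, amino acid uptake, catabolism and biosynthesis, nitrogen, phosphate, sulfur, polyamines, oxidative stress, heat shock, ribosomal proteins, ATP synthase and respiration, efflux, exopolysaccharides, type VI secretion, polyhydroxyalkanoate, osmoprotectants, fatty acid degradation, metals, PQQ, c-di-GMP, sigma factors, prophage, transposable elements, cell division and nucleotide synthesis. A match inside longer words for the polyhydroxyalkanoate pattern, and matches to protein family names, were corrected before group values were seen. A gene can belong to several lists. No locus tag of the array files (0 of 5350) matched the reference table, so names and coordinates are those of the array files, and 1679 genes are hypothetical proteins there. All columns of the series table matched a sample.

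The alternatives were no background correction, a normexp offset of 16, median scaling, cyclic loess, the mean of probes, the deposited series table, the deposited calls files, leaving out dim genes, fitting only the arrays compared, replicate letters as a block in 3 forms, array weights, an intensity trend with a robust prior, a minimum of 2-fold, and each array left out in turn. Added after the data were seen were the fits without both 48 h arrays of replicate A or B, the range of image numbers in the file headers as a block, the brighter genes alone, and the lists under 6 other scalings and by image-number range. The minimum of 2-fold was applied to counts of genes only, and the settings counted for named genes leave it out. No scaling moved the median of all genes by 0.1 log2 in any comparison.

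The fit was tested on simulated data for the 120 h plant comparison over 5350 genes, with 200 changed genes. Of genes changed 1.5-fold, 9 of 33 bright and 0 of 34 dim ones were recovered, of those changed 2-fold 17 of 31 and 3 of 36, and of those changed 4-fold 28 of 31 and 20 of 35. A true log2 change of 1 was estimated at a median of 0.52 for bright and 0.22 for dim genes, and 3 of 5150 unchanged genes were called. All simulated arrays had the same ratio of signal to background, while in the data it differed between arrays. The simulation therefore does not test false calls from such a difference. A simulated list of 30 genes shifted by 0.5 was called with both forms of camera. Its genes had independent noise, and the shift was added after the probes were combined. The simulation therefore does not test lists of correlated genes. In the data the estimated correlation was 0.41 for heat shock and 0.61 for polyhydroxyalkanoate. Text, lists and figures were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.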

Results

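Transcript levels of the soil bacterium Pseudomonas putida KT2440 were measured on 12 single-colour arrays. The bacteria had been scraped from agar plates of diluted M9 mineral medium with glucose, on which Arabidopsis thaliana plants either grew or were absent, after 48 h or 120 h. Each of the 4 combinations of plant and time held 3 biological replicates, named A, B and C. The question named by the series title is which genes of this bacterium are expressed differently in the rhizosphere, the zone around plant roots. All changes are given as log2 differences of normalized array intensity ± the standard error of the fit, with n = 3 arrays per group.

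Each array measured 5350 genes with 18 probes each, printed in 4 blocks. The number of arrays limits the precision of every value. Raw median intensity lay between 902 (plants at 48 h, replicate A) and 1946 (controls at 48 h, replicate B). The ratio of the 99th percentile to the modal intensity, a measure of how far bright genes stood above background, was 3.36 on the control array 48 h B and 6.17 to 7.64 on the other 5 arrays of 48 h. At 120 h that ratio was 4.88, 3.55 and 4.06 on the control arrays A, B and C, and 7.76, 3.89 and 8.39 on the plant arrays. After normalization the median gene lay at a log2 level of 8.05 and the 10th percentile at 7.70, and 1546 genes (28.9%) were more than 1 log2 unit above that percentile in some group. Folds of genes near this background are understated.

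At 48 h, 5 genes of a chromosomal cluster and 1 gene elsewhere were higher where plants were present. PP3783 rose by 1.65 ± 0.24 (3.13-fold) and PP3785 by 1.45 ± 0.21 (2.74-fold), both annotated as hypothetical proteins. PP3778, annotated as a pyrroline-5-carboxylate reductase, an enzyme of the last step of proline synthesis, rose by 1.22 ± 0.18 (2.32-fold). PP3775, a putative sarcosine oxidase, rose by 0.98 ± 0.16, and the aminotransferase PP3786 by 0.91 ± 0.14. The level of PP3785 went from 9.26 ± 0.23 without plants to 10.71 ± 0.13 with plants (SD, n = 3). Outside the cluster, the flavin reductase domain protein PP2697 rose by 1.29 ± 0.19. These were the 6 genes past an adjusted p of 0.05 in limma (adjusted p = 0.0235, and 0.0428 for PP3775), all higher with plants, and for each the 3 plant arrays lay above the 3 control arrays.

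The cluster PP3775 to PP3788 spans positions 4303152 to 4317469 of the chromosome in the coordinates of the array files. It was singled out after its values were seen. The cluster also holds the coproporphyrinogen oxidase family gene PP3781 (1.55 ± 0.27, adjusted p = 0.0583) and the putative non-ribosomal peptide synthetase PP3788, from a family of enzymes that build peptides without ribosomes (1.01 ± 0.22, adjusted p = 0.204). Next to PP2697, the gene PP2698, annotated as a homocysteine methyltransferase of methionine synthesis, stood at 1.76 ± 0.30 (adjusted p = 0.0529). At 120 h, 10 genes of the cluster rose: PP3775 by 1.27, PP3776 by 1.08, PP3777 by 0.82, PP3778 by 1.33, PP3779 by 1.42, PP3782 by 1.15, PP3783 by 1.16, PP3784 by 1.16, PP3785 by 1.15 and PP3786 by 0.58. For none of the cluster's genes did the plant effect differ between the times in the test of that difference.

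The list of ATP synthase and respiratory chain genes, 29 genes of energy conservation, rose at 48 h with a mean of 0.30 (camera, adjusted p = 9.49e-12). With an estimated correlation its adjusted p = 0.0278. Its members ATP synthase subunit A, PP5419, at 0.59 ± 0.12 (adjusted p = 0.154) and subunit epsilon, PP5412, at 0.54 ± 0.12 (adjusted p = 0.204) did not pass as single genes. None of the 29 passed over all genes, and 7 passed adjusted over the list alone. Nitrogen assimilation genes rose with a mean of 0.15 (adjusted p = 0.0017; adjusted p = 0.505 with an estimated correlation), where urease alpha PP2845 stood at 0.31 ± 0.11 and nitrite reductase PP1705 at 0.35 ± 0.14. Amino acid uptake genes rose with a mean of 0.07 (adjusted p = 0.0246; adjusted p = 0.505 with an estimated correlation), with the permease PP1299 at 0.33 and the dipeptide-binding protein PP0884 at 0.27. Prophage genes fell with a mean of -0.05 (adjusted p = 0.0395; adjusted p = 0.649 with an estimated correlation), with the capsid protein PP1567 at -0.39 and the portal protein PP1565 at -0.24, and this call held in 3 of 6 other scalings. In these 3 lists no gene passed in limma over all genes or adjusted over the list alone, where 193 of all genes had an unadjusted p under 0.05. The call for amino acid uptake was lost without control 48 h A, plant 48 h B or control 48 h C (mean 0.05 each), and that for prophage genes without control 48 h B (-0.01), plant 48 h B (-0.03) or plant 48 h C (-0.05), and without both 48 h B arrays the prophage mean turned to 0.0097 (adjusted p = 0.884). The other lists had an adjusted p between 0.109 (flagellum) and 0.713 (ribosomal proteins).

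Single values at 48 h were large but variable for some iron and oxidative stress genes. The siderophore biosynthesis gene PP4245 stood at 1.16 ± 0.37 (adjusted p = 0.919) and the manganese superoxide dismutase PP0946, which removes superoxide, at 1.24 ± 0.67 (adjusted p = 0.9999). In all, 193 genes had an unadjusted p under 0.05, against 267.5 expected by chance. The count of 6 rested on single arrays: it was 0 without control 48 h A, plant 48 h B, control 48 h C, plant 48 h C or control 120 h A, 1 without plant 48 h A, 35 without control 48 h B and 14 without plant 120 h A. It was also 0 in limma under median scaling, cyclic loess or the deposited calls files, 1 from the deposited normalized values and 2 from the 48 h arrays alone, where limma's unadjusted count for the settings with 0 ranged from 137 to 298. The 48 h replicate A arrays came from a lower range of image numbers than the other 10 arrays, with 1 array per group and so no test within it. With that range as a block the count was 0, and within the upper range it was 0. The mean of the ATP synthase list was 0.30 with the block (adjusted p = 1.34e-11) and 0.32 within the upper range (adjusted p = 6.84e-08). All 4 lists called at 48 h held with the block, which leaves the 48 h means unchanged because the lower range holds 1 array of each group. Within the upper range 3 held, and amino acid uptake, at 0.06, lost its call in camera (adjusted p = 0.147, against 0.0171 with the block). In that range 3 further lists passed, the TCA cycle at 0.20 (adjusted p = 0.0015), flagellum at 0.06 (adjusted p = 0.0363) and aromatic compound catabolism at -0.09 (adjusted p = 0.0302).

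**Figure D1:**
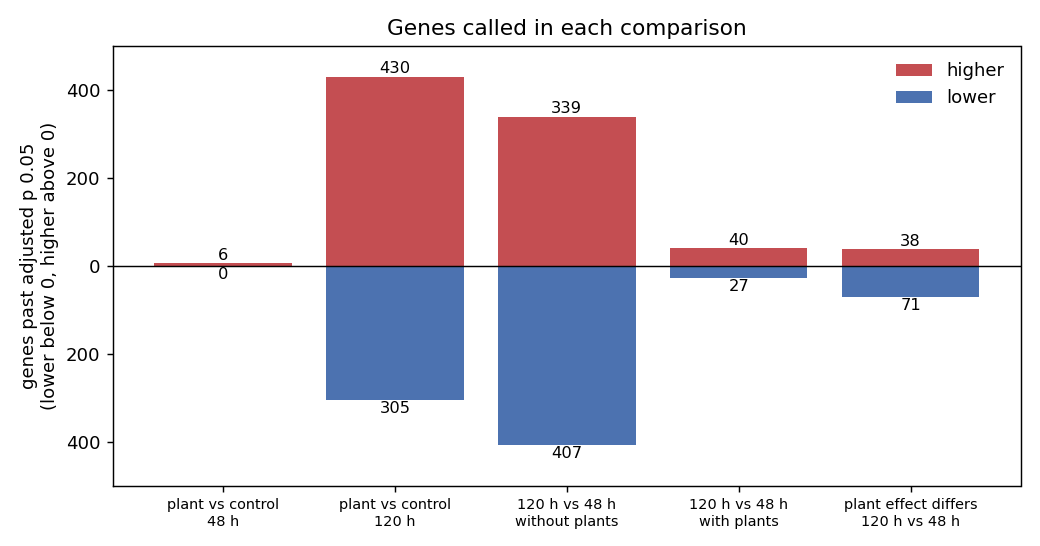
Bars give the number of genes past an adjusted p of 0.05 in limma in each of the 5 comparisons, separately for higher and lower genes (y axis: number of genes). The plant effect had 6 genes at 48 h and 735 at 120 h.

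At 120 h the presence of plants went with a broad difference. The neighbouring genes for the A and B subunits of a putative CoA-transferase, PP3122 and PP3123, rose by 2.39 ± 0.17 (5.24-fold, adjusted p = 5.20e-06) and 2.39 ± 0.20 (5.23-fold, adjusted p = 1.45e-05). The level of PP3122 was 9.21 ± 0.09 without plants and 11.60 ± 0.33 with plants (SD, n = 3). The hypothetical proteins PP1659 and PP1660 rose by 2.51 ± 0.46 and 2.08 ± 0.27, the outer membrane channel porin D, PP1206, by 2.35 ± 0.41, and the acyl-transferase PP1408 by 2.19 ± 0.34. The amino acid-binding protein PP0282 rose by 1.92 ± 0.33, and the flagellar rod protein PP4390 by 1.93 ± 0.23. Isocitrate lyase, PP4116, which opens the glyoxylate shunt, rose by 1.93 ± 0.43 (adjusted p = 0.0097), a call lost without background correction (0.95, adjusted p = 0.0672; 0.0019 to 0.0672 over all its settings). The ferripyoverdine receptor PP4217, which takes up the iron-loaded siderophore pyoverdine, rose by 1.93 ± 0.46 (adjusted p = 0.0135), a call lost without background correction (0.79), with the deposited calls files (0.66) and without control 120 h A (1.89; adjusted p from 3.71e-04 to 0.178 over all its settings).

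The largest differences were in genes lower with plants. PP4858 fell by 5.16 ± 0.32 on the log2 scale (35.6-fold, adjusted p = 3.79e-06), from 13.33 ± 0.34 without plants to 8.17 ± 0.09 with plants (SD, n = 3). PP4557 fell by 4.93 ± 0.32 (30.5-fold), and both are hypothetical proteins. IbpA, PP1982, a small heat shock chaperone, fell by 3.98 ± 0.34 (15.8-fold, adjusted p = 1.53e-05), from 13.86 ± 0.44 to 9.87 ± 0.29. The hypothetical proteins PP0153, PP1662 and PP0737 changed by -3.52 ± 0.55, -3.20 ± 0.40 and -2.91 ± 0.21. The LysE family transporter PP0699, of a family of amino acid exporters, fell by 3.40 ± 0.26, and the major facilitator transporter PP5072 fell by 3.05 ± 0.27. The outer membrane protein H1, PP1185, fell by 3.35 ± 0.57 to a level near background. MucA, PP1428, the regulator that holds the envelope stress sigma factor AlgU inactive, fell by 2.87 ± 0.31. The rule that chose these 20 genes required the 3 plant arrays to lie on one side of the 3 control arrays.

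**Figure D2:**
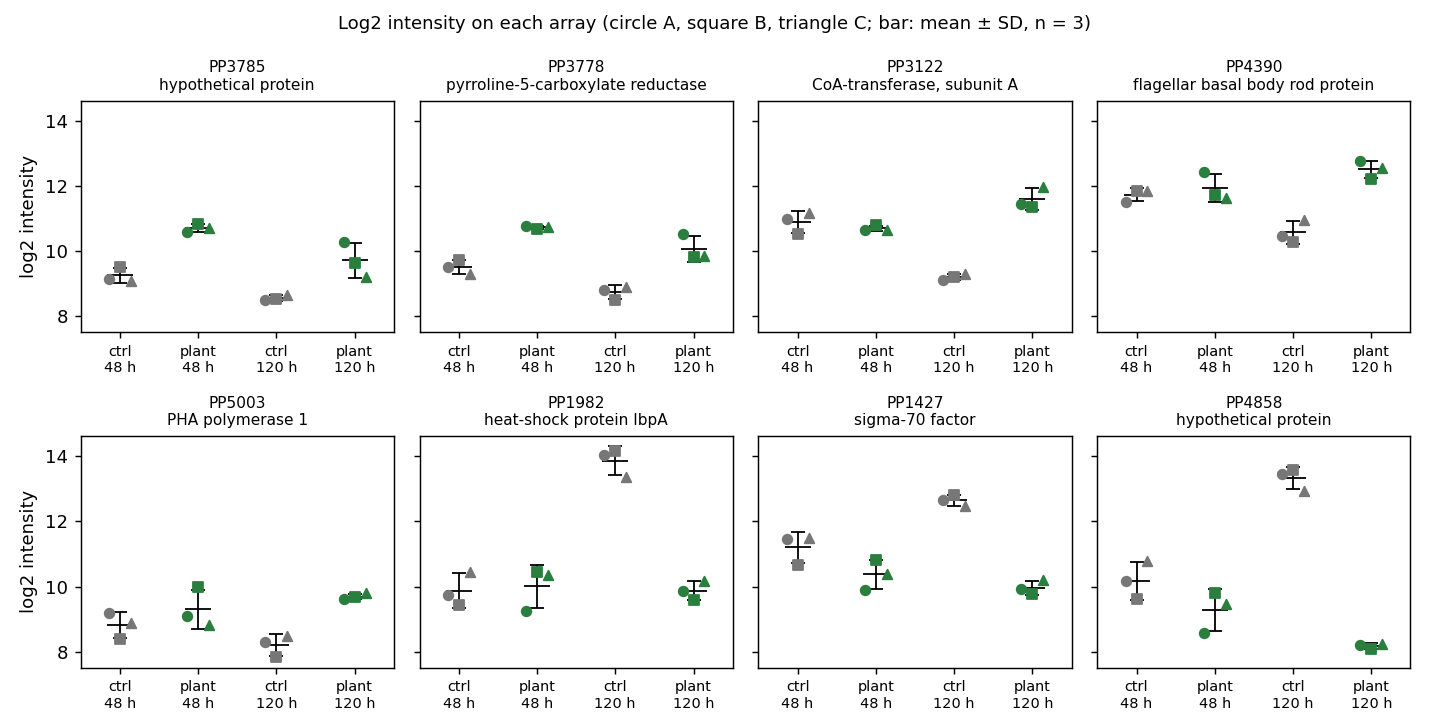
Points give the normalized log2 intensity on each array for 8 genes in the 4 groups, with lines at the mean ± SD (n = 3). PP1982 and PP4858 stood higher in the 120 h controls than in the other groups, at 13.86 and 13.33.

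Of 43 flagellum genes, 15 rose at 120 h and none fell (16 and 0 adjusted over the list alone), with a mean of 0.41 (camera, adjusted p = 4.10e-08). The adjusted p = 0.0543 with an estimated correlation. The rod protein PP4391 rose by 1.90 ± 0.20, the hook protein PP4388 by 1.37 ± 0.15 and the filament cap protein FliD, PP4376, by 1.35 ± 0.25. The chemotaxis list of 37 genes had 6 higher and 0 lower members, the same adjusted over the list alone, and was not called as a list (mean 0.09, adjusted p = 0.220). Its members CheV, PP4393, and CheZ, PP4339, rose by 0.87 ± 0.14 and 0.59 ± 0.11.

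Of the 29 ATP synthase and respiratory chain genes, 13 rose at 120 h and 1 fell (21 and 5 adjusted over the list alone), with a mean of 0.56 (adjusted p = 1.02e-06). The adjusted p = 0.0543 with an estimated correlation. ATP synthase subunit I, PP5420, rose by 1.62 ± 0.29, subunit B, PP5417, by 1.44 ± 0.24, subunit C, PP5418, by 1.25 ± 0.24 and subunit A, PP5419, by 1.06 ± 0.12. The member that fell was subunit II of the cytochrome o ubiquinol oxidase, PP0812, by 0.57.

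All 5 genes of the polyhydroxyalkanoate list, which make, degrade and coat granules of a carbon storage polymer, rose at 120 h (all 5 adjusted over the list alone), with a mean of 1.19 (adjusted p = 2.02e-05). The adjusted p = 0.186 with an estimated correlation. Polymerase 1, PP5003, rose by 1.48 ± 0.27 (2.80-fold) from 8.21 ± 0.34 to 9.69 ± 0.09, the granule-associated proteins PP5008 and PP5007 by 1.39 ± 0.21 and 1.28 ± 0.25, and the depolymerase PP5004 rose 2.14-fold.

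Of 22 heat shock and protease genes, 14 fell at 120 h and 1 rose (14 and 3 adjusted over the list alone), with a mean of -0.84 (adjusted p = 2.76e-05). The adjusted p = 0.397 with an estimated correlation. Besides IbpA, the putative heat shock protein PP3313 fell by 1.87 ± 0.30, the HSP20 family protein PP3314 by 1.82 ± 0.30 and PP3312 by 1.63 ± 0.27. The chaperonin GroEL, PP1361, fell by 1.44 ± 0.24, and DnaK, PP4727, by 1.12 ± 0.21. The member that rose, CsuC (PP2361, 0.48), is a chaperone of pilus assembly, not a heat shock protein.

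Of 90 amino acid uptake genes 19 rose at 120 h and none fell (20 and 0 adjusted over the list alone), with a mean of 0.22 (adjusted p = 7.67e-04). The adjusted p = 0.186 with an estimated correlation. The dipeptide-binding protein PP0885 rose by 1.74 ± 0.21, and the binding proteins PP1297 for amino acids and PP4867 for branched-chain amino acids by 1.71 ± 0.35 and 1.65 ± 0.35. Of 25 polyamine genes 6 rose and none fell (8 and 0 adjusted over the list alone), with a mean of 0.25 (adjusted p = 0.0073; adjusted p = 0.203 with an estimated correlation). The putrescine-binding protein PP5181 rose by 1.63 ± 0.23 and the polyamine-binding protein PP3845 by 0.70 ± 0.14. Of 27 genes of nitrogen assimilation 6 rose and none fell (9 and 0 adjusted over the list alone), with a mean of 0.27 (adjusted p = 0.0264; adjusted p = 0.445 with an estimated correlation), a call held in 4 of 6 other scalings, with 0.0761 as the highest adjusted p. It was lost without plant 120 h A (mean 0.24), control 120 h B (0.22) or plant 120 h C (0.22). NtrB, PP5047, the sensor kinase of the nitrogen limitation response, rose by 1.33 ± 0.23, and its response regulator NtrC, PP5048, by 0.72 ± 0.16. The ammonium transporter PP5233 rose by 1.56 ± 0.39 (adjusted p = 0.0182), a call kept in 24 of 30 settings, and NtrC lost its call without plant 120 h C (0.59).

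Of 28 genes of glucose and gluconate metabolism, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with a mean of 0.27 (adjusted p = 0.0021). The adjusted p = 0.0543 with an estimated correlation. Genes for 2-ketogluconate, a product of periplasmic glucose oxidation, were among them: the kinase PP3378 rose by 1.09 ± 0.09 (adjusted p = 1.79e-05), the transporter PP3377 by 1.16 ± 0.25, a call lost with the calls files (0.38), and the regulator PtxS, PP3380, by 0.93 ± 0.19. Glucose-6-phosphate dehydrogenase, PP1022, rose by 1.23 ± 0.36 (adjusted p = 0.0400), a call kept in 16 of 30 settings.

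**Figure D3:**
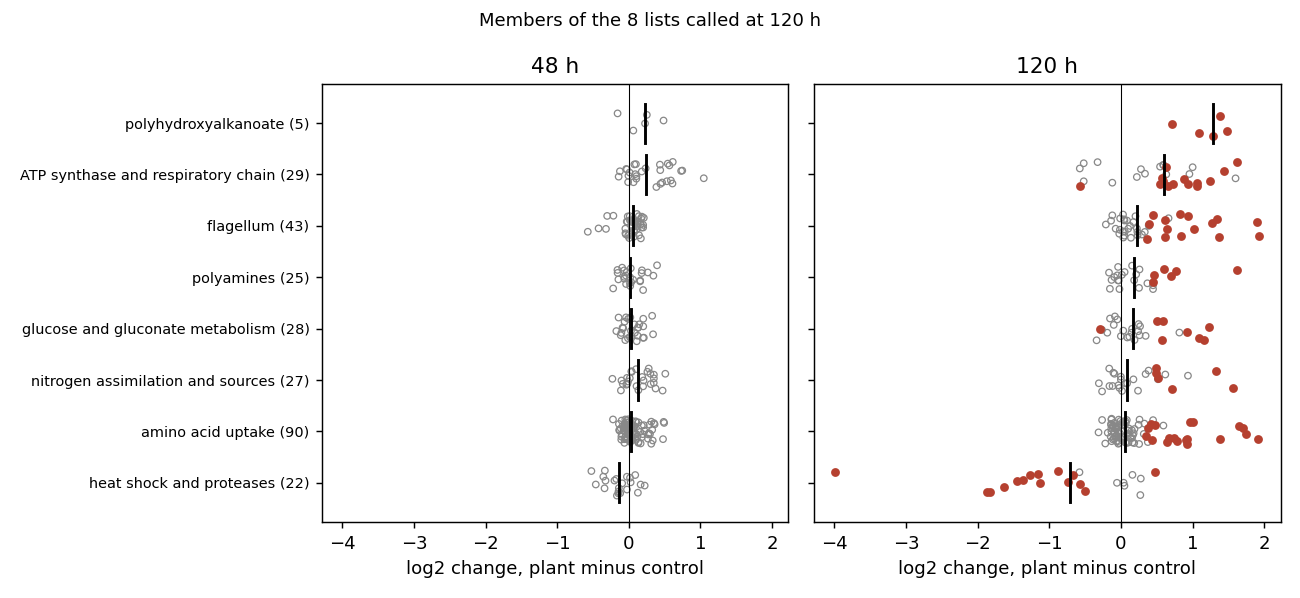
Points give the log2 change of each member of the 8 lists called at 120 h (x axis: log2 plant minus control, at 48 h and at 120 h), filled in red where a gene passed an adjusted p of 0.05, with a black tick at the list's median. At 120 h the median of the heat shock list was -0.71 and that of the polyhydroxyalkanoate list 1.28. In all 6 other scalings the mean of each of the 8 lists kept its sign at 120 h.

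Several lists held strongly changed genes without passing as lists at 120 h. Of 42 genes in the sigma factor list 2 rose and 9 fell, the same adjusted over the list alone, with a mean of -0.23 (camera, adjusted p = 0.0601). The list also takes genes whose product text only names a sigma factor, such as the AlgU regulator MucA, so not all are sigma factors. Its members include the sigma-70 factor PP1427, which lies beside mucA and fell by 2.68 ± 0.24, and AlgN, PP1429, which fell by 1.79 ± 0.28. Of 24 genes of the TCA cycle and glyoxylate shunt 4 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0601), among them the succinyl-CoA synthetase subunit PP4185, which rose by 1.20 ± 0.26, a call lost with the calls files (0.82). Of 27 genes of cell division and DNA replication 4 rose and none fell, the same adjusted over the list alone (adjusted p = 0.0601), among them FtsA, PP1341, which rose by 0.95 ± 0.16, and MinD, PP1733, by 0.73 ± 0.13. Of 37 genes of aromatic compound catabolism 2 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.0601), with the benzoate dioxygenase subunits PP3162 and PP3161 lower by -1.02 ± 0.13 and -0.89 ± 0.15. Of 26 genes of exopolysaccharides and adhesion 1 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.0802), with the alginate activator gene PP4470 at -0.74 ± 0.21, a call kept in 21 of 30 settings and lost without any 1 of the 6 arrays of 120 h.

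Lists without a call at 120 h also held single changed genes. In amino acid biosynthesis (18 genes, 2 higher and 2 lower, the same adjusted over the list alone, adjusted p = 0.991) the beta subunit of tryptophan synthase, PP0083, fell by 2.14 ± 0.32 and the alpha subunit, PP0082, by 0.88 ± 0.18. In amino acid catabolism arginine deiminase, PP1001, which releases ammonia from arginine, rose by 1.73 ± 0.29. Of that list's 17 genes 3 were higher and 1 lower (5 and 3 adjusted over the list alone), with an adjusted p = 0.506 in camera. The lower one, at -0.84, was the gamma-aminobutyrate transporter PP4106. It matched this list by its name and is not in the amino acid uptake list. Among 75 efflux genes (4 higher and 5 lower, the same adjusted over the list alone, adjusted p = 0.542) the 3 neighbouring multidrug efflux genes PP1271, PP1272 and PP1273 fell by 1.46 ± 0.20, 1.01 ± 0.11 and 0.87 ± 0.10. Among 57 ribosomal protein genes (6 higher and 3 lower, the same adjusted over the list alone, adjusted p = 0.249) S15, PP4709, fell by 1.62 ± 0.19 and L34, PP0009, rose by 0.77 ± 0.18. In oxidative stress (35 genes, 1 higher and 2 lower; 1 and 1 adjusted over the list alone; adjusted p = 0.879) the putative catalase PP2887 fell by 1.59 ± 0.14, to near background. In fatty acid degradation (38 genes, 2 higher and 3 lower, the same adjusted over the list alone, adjusted p = 0.371) the acyl-CoA dehydrogenase family gene PP0370 fell by 1.51 ± 0.28. In osmoprotectants and trehalose (28 genes, 5 higher and 2 lower; 6 and 4 adjusted over the list alone; adjusted p = 0.723) the putative trehalose synthase PP4059 rose by 0.70 ± 0.10.

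Iron uptake stayed without a list call at 120 h. Of 38 siderophore receptor and iron uptake genes 1 rose over all genes and none adjusted over the list alone (adjusted p = 0.991), namely the inner membrane protein PP5307 of a ferric siderophore transport system, at 1.33 ± 0.39, a call kept in 16 of 30 settings. The pyoverdine list held only PP4217 and the export protein PP4216 (0.55, adjusted p = 0.180) and was too short to test. The type VI secretion list held 3 VgrG proteins, PP2614, PP3386 and PP4049, at -0.24, 0.04 and -0.14, none past the threshold, and was not tested either. Of 21 phosphate starvation genes 1 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.506), and of 21 genes of PQQ and alcohol oxidation 2 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.723). Of 56 metal resistance genes 1 fell, also adjusted over the list alone (adjusted p = 0.363), the zinc-containing alcohol dehydrogenase PP2827, an enzyme rather than a resistance gene. Of 38 sulfur genes 1 rose, none adjusted over the list alone (adjusted p = 0.889), and of 21 c-di-GMP genes 1 rose, also adjusted over the list alone (adjusted p = 0.441). None of 20 nucleotide synthesis genes passed by either count (adjusted p = 0.991), of which PP4822 stood at 0.26 ± 0.09. Of 67 prophage genes 2 rose and none adjusted over the list alone (adjusted p = 0.248), and of 69 transposable element genes 4 rose, 2 of them adjusted over the list alone (adjusted p = 0.248). Transposase copies share sequence, so that their probes can bind each other's transcripts. Mean, median and test differed in sign for amino acid biosynthesis (mean -0.08, test upward), oxidative stress (mean 0.01, test downward), amino acid catabolism (median -0.02, mean 0.17), osmoprotectants (median -0.01, mean 0.05), c-di-GMP turnover and siderophore receptors (medians of 0.00 and -0.05 beside means of 0.07 and 0.08).

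In total 735 of 5350 genes passed an adjusted p of 0.05 in limma at 120 h, 430 higher and 305 lower (58.5% higher), 208 of them by at least 2-fold, and 264 are hypothetical proteins. Of 111 named genes with a call at 120 h, 75 kept it in every alternative setting other than the minimum of 2-fold, which was not applied to single genes. The share of higher genes moved with the scaling, to 68.9% of 479 genes (330 higher and 149 lower) under median scaling, 44.5% of 741 (330 and 411) under cyclic loess and 42.9% of 793 (340 and 453) with the calls files. The count was 436 without control 120 h A, 439 without control 120 h B, 469 without plant 120 h C, 488 without plant 120 h A and 1614 with array weights. With the image-number range as a block it was 717, and within the upper range 761, and all 8 lists held their calls in both. No 120 h array lay in the lower range, so these fits leave the 120 h changes as they were and alter only the spread. They are no check of the 120 h effect against that range. With an estimated correlation 0 of the 30 lists passed camera at 120 h, where 7 had an unadjusted p under 0.05 and fry called 11.

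Between 48 h and 120 h without plants, IbpA, PP1982, rose by 3.98 ± 0.34 (15.8-fold, adjusted p = 6.97e-05), and of the 22 heat shock genes 13 rose and none fell (15 and 1 adjusted over the list alone; mean 0.96, adjusted p = 2.29e-08). The adjusted p = 0.417 with an estimated correlation. PP4858 and PP4675, hypothetical proteins, rose by 3.15 ± 0.32 and 2.81 ± 0.37, tryptophan synthase beta, PP0083, by 2.81 ± 0.32 and PP0370 by 2.72 ± 0.28. Porin D, PP1206, fell by 2.65 ± 0.41, the acyl-transferase PP1408 fell by 2.60 ± 0.34, and the hypothetical proteins PP3089, PP5390 and PP2292 by 2.37 ± 0.29, 2.34 ± 0.61 and 2.32 ± 0.32, of which PP5390 kept its call in 20 of 29 settings.

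Other lists were also called over time without plants. Fatty acid degradation rose (7 of 38 genes higher, also adjusted over the list alone; mean 0.27, adjusted p = 0.0044; adjusted p = 0.652 with an estimated correlation). The polyhydroxyalkanoate list fell (2 of 5 genes lower, 5 adjusted over the list alone; mean -0.90, adjusted p = 0.0017; adjusted p = 0.417 with an estimated correlation). Amino acid uptake fell (17 of 90 lower, also adjusted over the list alone; mean -0.18, adjusted p = 0.0245; adjusted p = 0.417 with an estimated correlation). Flagellum (10 of 43 lower and 1 higher, 13 and 1 adjusted over the list alone; mean -0.26), polyamines (6 of 25 lower and 1 higher, 9 and 1 adjusted over the list alone; mean -0.23) and ATP synthase (9 of 29 lower and 3 higher, 10 and 3 adjusted over the list alone; mean -0.27) fell with an adjusted p = 0.0365 each. With an estimated correlation they had an adjusted p = 0.439, an adjusted p = 0.417 and an adjusted p = 0.439. Aromatic compound catabolism rose (4 of 37 higher and 1 lower, the same adjusted over the list alone; mean 0.14, adjusted p = 0.0484; adjusted p = 0.809 with an estimated correlation). The calls for these last 4 lists held in 2, 3, 3 and 3 of 6 other scalings.

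In total 746 genes differed over time without plants, 339 higher and 407 lower (45.4% higher). The share was 61.8% under cyclic loess (421 higher and 260 lower) and 57.7% with the calls files (479 and 351), and the count was 305 under median scaling, 1129 with array weights, 401 without control 120 h A, 467 without control 120 h B and 469 without control 48 h C. With the image-number range as a block it was 669 and within the upper range 659, and 8 and 5 of the 8 lists held. Of the 430 genes higher with plants at 120 h, 239 were among the 407 lower over time without plants, where independent lists would share 32.7. Of the 305 lower with plants, 196 were among the 339 higher over time, against 19.3. Across genes the correlation of the 120 h plant effect with the time change was -0.80, and -0.50 in simulated unchanged groups that shared the 120 h control arrays in the same way. Its covariance was -0.15, against -0.01 in the simulations. In the 6 ways to split the 3 control 120 h arrays so that no array was in both comparisons, a test chosen after the values were seen, the covariance lay between -0.15 and -0.12 and the correlation between -0.78 and -0.68. These correlations are across genes, which are not independent replicates.

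With plants fewer genes passed the threshold over time. Isocitrate lyase, PP4116, rose by 2.46 ± 0.43 (5.49-fold, adjusted p = 0.0228), the 3-hydroxybutyryl-CoA dehydrogenase PP3755 by 1.98 ± 0.36, PP2019 by 1.83 ± 0.35, PP0370 by 1.81 ± 0.28 and the electron transfer flavoprotein-ubiquinone oxidoreductase PP4203 by 1.76 ± 0.36. PP1662 fell by 3.39 ± 0.40 (adjusted p = 0.0038), PP1185 fell by 2.70 ± 0.57, PP4557 by 1.78 ± 0.32, the response regulator PP2907 by 1.75 ± 0.21 and PP3782 by 1.66 ± 0.33. Among these 10 genes, PP1662 and PP2907 kept their calls in all 29 settings, and the other 8 lost theirs without plant 48 h C and without plant 120 h C. Fatty acid degradation rose as a list (2 of 38 genes higher, 7 adjusted over the list alone; mean 0.26, adjusted p = 1.05e-04; adjusted p = 0.594 with an estimated correlation). Flagellum rose (2 of 43 higher, also adjusted over the list alone; mean 0.13, adjusted p = 0.0018; adjusted p = 0.524 with an estimated correlation). Heat shock rose (none of 22 past the threshold by either count; mean 0.26, adjusted p = 0.0018; adjusted p = 0.816 with an estimated correlation), and prophage genes fell (none of 67 by either count; mean -0.07, adjusted p = 0.0322; adjusted p = 0.860 with an estimated correlation).

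In total 67 genes differed over time with plants, 40 higher and 27 lower (59.7% higher). The count was 9 from the arrays with plants alone, 22 under median scaling (18 higher and 4 lower, 81.8% higher), 30 with the calls files (22 and 8, 73.3% higher), 162 under cyclic loess, 302 with array weights, 102 with an intensity trend and robust prior, 5 without plant 48 h C, 6 without plant 120 h C, 18 without plant 120 h B, 104 without plant 120 h A and 136 without control 48 h B. With the image-number range as a block it was 39 and within the upper range 40, and 3 and 1 of the 4 lists held. Whether the time change was smaller with plants is the same contrast as the difference of plant effects between the times, which follows.

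The plant effect differed between the times for 109 genes, 38 of them with a higher and 71 with a lower effect at 120 h (34.9% higher). The CoA-transferase genes PP3122 and PP3123 had differences of 2.59 ± 0.24 (adjusted p = 5.02e-04) and 2.42 ± 0.28, with plant effects of -0.20 and -0.03 at 48 h. PP1408 differed by 2.20 ± 0.48, PP3109 by 1.81 ± 0.39 and FliD, PP4376, by 1.77 ± 0.35. PP4858 differed by -4.25 ± 0.45 (adjusted p = 5.47e-04), PP4557 by -4.16 ± 0.45, IbpA, PP1982, by -4.11 ± 0.48, PP0153 by -3.49 ± 0.78 and PP0699 by -2.98 ± 0.37. All 109 genes passed at 120 h, none at 48 h, where 193 had an unadjusted p under 0.05 in limma, and 46 had opposite signs at the times. Of these 10 named genes 5 kept their calls in all 29 settings, while PP0699 kept it in 28, PP4376 in 21, PP0153 and PP1408 in 14 each and PP3109 in 12. All 5 of these lost the call under median scaling, and PP0153, PP1408 and PP3109 also without background correction, with the deposited values and with the calls files. PP0153, PP1408, PP3109 and PP4376 lost it without control 120 h A and without control 120 h B, among other single arrays. The count was 18 under median scaling (4 and 14, 22.2% higher), 143 under cyclic loess (21 and 122, 14.7%), 152 with the calls files (36 and 116, 23.7%), 417 with array weights, 67 without control 48 h A, 61 without plant 48 h C, 46 without control 120 h A, 57 without plant 120 h A, 43 without control 120 h B and 58 without plant 120 h C. With the image-number range as a block, which leaves these differences unchanged and alters only the spread, the count was 103, and within the upper range 121.

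Gene lists differed between the times as well. The difference was upward for flagellum (8 of 43 genes, 11 adjusted over the list alone; mean 0.39, adjusted p = 1.21e-06; adjusted p = 0.107 with an estimated correlation). It was upward for the polyhydroxyalkanoate list (1 of 5, 4 adjusted over the list alone; mean 1.02, adjusted p = 6.17e-05; adjusted p = 0.283 with an estimated correlation). Heat shock genes differed downward (1 of 22, 10 adjusted over the list alone; mean -0.70, adjusted p = 6.17e-05; adjusted p = 0.428 with an estimated correlation). Glucose metabolism (1 of 28, also adjusted over the list alone; mean 0.21, adjusted p = 0.0110; adjusted p = 0.107 with an estimated correlation) and chemotaxis (1 of 37, also adjusted over the list alone; mean 0.12, adjusted p = 0.0382; adjusted p = 0.283 with an estimated correlation) differed upward. Amino acid uptake (0 of 90, 4 adjusted over the list alone; mean 0.15, adjusted p = 0.0222; adjusted p = 0.329 with an estimated correlation) and polyamines (0 of 25, 5 adjusted over the list alone; mean 0.21, adjusted p = 0.0229; adjusted p = 0.329 with an estimated correlation) also differed upward. ATP synthase genes differed upward (0 of 29 by either count; mean 0.25, adjusted p = 0.0382; adjusted p = 0.377 with an estimated correlation), and sigma factors downward (2 of 42, 8 adjusted over the list alone; mean -0.20, adjusted p = 0.0382; adjusted p = 0.329 with an estimated correlation). With the image-number range as a block, which leaves the mean differences unchanged, all 9 lists held, and within the upper range 4 did. Calls for ATP synthase, polyamines and sigma factors held in 3, 4 and 4 of 6 other scalings, and for amino acid uptake, chemotaxis and glucose metabolism in 5.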

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

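Chosen only after results were seen were the list tests of the difference of plant effects, the fits without a pair of arrays, the exchange measure for replicates A and C, the positions of single arrays, the slopes and cluster means of single replicates, the tests of brightness range under median scaling and cyclic loess, the split of the control arrays, the grouping of splits by their 120 h groups, the level of genes lower with plants, the counts of matching signs and the slopes in other scalings, and the remaining tests were set before their results were seen.

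The plant effect differed between 120 h and 48 h for 109 genes by the test of the difference itself. Among named genes the difference of log2 plant effects was positive for the CoA-transferase subunits PP3122 (2.59) and PP3123 (2.42), PP1408 (2.20), the flagellar genes PP4390 (1.73), PP4391 (1.73), PP4388 (1.16) and PP4376 (1.77), CheV PP4393 (0.93), PP3109 (1.81), the granule-associated protein PP5008 (1.54), the outer membrane efflux protein PP4923 (0.84) and the 2-ketogluconate kinase PP3378 (0.76). It was negative for PP4858 (-4.25), PP4557 (-4.16), IbpA PP1982 (-4.11), PP0153 (-3.49), PP0699 (-2.98), PP0737 (-2.75), PP5072 (-2.63), MucA PP1428 (-2.12) with the sigma-70 factor PP1427 (-1.84), tryptophan synthase beta PP0083 (-2.12), the catalase PP2887 (-1.58), S15 PP4709 (-1.41), the efflux genes PP1271 (-1.28), PP1272 (-0.82) and PP1273 (-0.78), the aminobutyrate transporter PP4106 (-1.03), and the benzoate dioxygenase genes PP3162 (-1.01) and PP3161 (-0.92). Mean differences of lists were 0.39 for flagellum, 1.02 for polyhydroxyalkanoate, 0.25 for ATP synthase, 0.21 for glucose, 0.21 for polyamines, 0.15 for amino acid uptake, 0.12 for chemotaxis, -0.70 for heat shock and -0.20 for sigma factors. Of 100 splits of the arrays within each time, 9 called as many genes as the real one, whose count was 109, with 558 as the highest other, so that chance is not excluded by this count. The 8 other splits with the real groups at 120 h all called at least 124 genes, and the 91 with mixed groups at 120 h at most 1, which points to the 120 h groups as the structure behind the count.

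Few genes differed between plant and control plates at 48 h, 6 in all and 44 without both B arrays. Exchanged labels of the replicate B arrays were tested on the 50 bright genes that most separated A and C. Replicate B showed a median -0.11 of their difference (bootstrap over genes -0.24 to -0.06, 17 of 50 genes with the same sign). That interval does not cover the spread between arrays. The same measure was -0.08 for replicate A from B and C and 0.79 for replicate C from A and B. Positions were taken on the axis from the 120 h controls (0) to the 120 h plants (1). There control 48 h B lay at 0.82 and plant 48 h B at 0.91, in the order of their labels. The slope of the 48 h difference on the 120 h effect was 0.09 for replicate B (0.05 to 0.13 over genes). It was 0.25 for A and 0.15 for C. The 3 control arrays of 48 h ranged on that axis from 0.67 to 0.82, more than the B arrays lay apart. Mean plant minus control at 48 h over PP3775 to PP3788 was 1.31, 0.90 and 1.15 log2 in replicates A, B and C. For B it went with the labels. This cluster was singled out after the values of these arrays were seen, so it does not decide. An exchange could neither be excluded nor shown, and no label was changed. Of the 10 splits of the 6 arrays, 2 called as many genes as the real one, with 6 genes, the other being the split with the B labels exchanged, with 92, several times the real count, which points to a structure of the samples, and 10 splits are too few for a share under 0.05. A wider spread stays open, with the within-group SD at 48 h 1.23 times that at 120 h (0.15 against 0.12). A smaller plant effect at 48 h is compatible with the slope of the 48 h on the 120 h effect, 0.16 over genes called at 120 h. Its interval of 0.14 to 0.18 is a bootstrap over genes and does not cover the spread between arrays. Single replicates gave 0.25, 0.09 and 0.15 (A, B, C). The sign was the same in 557 of 735 genes (75.8%), although choosing genes at 120 h lowers that slope.

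Many genes differed at 120 h, when the ratio of the 99th percentile to the modal intensity was 3.55 to 4.88 on the control arrays and 7.76, 3.89 and 8.39 on the plant arrays A, B and C. Quantile normalization gave all arrays nearly the same range, which fixes the balance of bright genes. The 39.7% of called genes brighter than the 75th percentile of genes that were lower with plants (189 of 476) therefore decides nothing. All 305 genes lower with plants were lower under median scaling, which leaves each array its range and would push bright genes up with plants. That is 100% (exact 95% interval over genes from 98.8%), with 149 called. All 430 higher genes were higher under cyclic loess, which removes trends with intensity (100%, from 99.1%). Of them 315 were called, and the median over all 430 was 0.55 against 0.69 as reported. These checks do not decide on the range as a cause. The genes were chosen as called on the same arrays, and ranges differed little under median scaling, so signs could hardly change. There the 99th percentile lay 4.19, 3.67 and 4.07 log2 above the median on control arrays and 4.31, 3.78 and 4.35 on plant arrays. Cyclic loess, like quantile normalization, evens out intensity differences between arrays. Plant nucleic acid binding to probes stays open. The median level in controls of the genes higher with plants lay at the 74.1st percentile of genes, just under the 75th percentile set as the bound. That of the genes lower with plants lay at the 88.5th, which does not test this explanation for them. Quantile normalization gives all arrays 1 distribution, so signal added to some probes can lower the values of others. A response of the bacteria to plants is the biological explanation the design names, and it stays possible as well. Of 10 splits, 1 reached the real count of 735, the real one, with 0 as the highest other, and 10 splits are too few for a share under 0.05.

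The plant effect at 120 h ran opposite to the time change without plants. The control 120 h arrays enter both comparisons and gave a covariance across genes of -0.15, against -0.01 in simulations of unchanged genes (lowest -0.0119, highest -0.0093, 100 simulations), and with these arrays split so that none was in both comparisons it was -0.14 (-0.15 to -0.12 over the 6 ways), which argues against the sharing as the cause. A candidate explanation is a time change that plants left smaller. Over genes called without plants, the slope of the time change with plants on that without was 0.25. Its interval of 0.21 to 0.30 is a bootstrap over genes and does not cover the spread between arrays. The sign was the same in 582 of 746 genes (78.0%), and the slope was 0.23 to 0.24 in 3 other scalings. Choosing genes by their change without plants lowers that slope, and an effect particular to the 120 h control plates would give the same picture and was not tested. For the time comparisons, 1 of 10 splits reached the real counts of 746 and 67, with 0 as the highest other in each, and 10 splits are too few for a share under 0.05.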

How the results depend on the processing

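The fits without both 48 h arrays of replicate A or B, the block of image-number range, the brighter genes alone and the list tests by scaling were chosen only after results were seen. Beyond the counts of genes and lists, 5827 values of named genes and lists kept their direction and side of the threshold, 548 lost the call, 21 gained one, 7 uncalled values changed sign and 1 called value reversed: the prophage list at 48 h stood at 0.0097 without both 48 h B arrays (adjusted p = 0.884; 0.0395 as reported). The cause of the differences was not tested except where fewer arrays or a fold minimum explain it. Signal over background limits all counts: on simulated data 3 of 36 dim genes changed 2-fold were recovered.

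The 6 genes at 48 h became 0 under median scaling, cyclic loess, the calls files, the image-number block and without both A arrays (unadjusted counts in limma 137 to 298 over all settings with 0), 1 with the deposited values, 2 from the compared arrays, 19 with array weights, 12 with a trended robust prior, 44 without both B arrays, and 0 to 35 with single arrays left out (35 without control 48 h B, 14 without plant 120 h A, 1 without plant 48 h A). The 735 genes at 120 h became 479 under median scaling, 1614 with array weights, 208 at 2-fold, and 436 to 833 with arrays left out (436 without control 120 h A, 439 without control 120 h B, 469 without plant 120 h C, 488 without plant 120 h A). The 746 over time without plants became 305 under median scaling, 1129 with array weights, 215 at 2-fold, and 401 to 842 with arrays left out (401 without control 120 h A, 467 without control 120 h B, 469 without control 48 h C).

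The 67 over time with plants became 22 under median scaling, 162 under cyclic loess, 30 with the calls files, 9 from the compared arrays, 302 with array weights, 102 with a trended robust prior, 31 at 2-fold, 173 without both B arrays, 40 without both A arrays, 39 with the image-number block, and 5 to 136 with arrays left out (5 without plant 48 h C, 6 without plant 120 h C, 18 without plant 120 h B, 104 without plant 120 h A, 136 without control 48 h B). The 109 genes of the difference became 18 under median scaling, 417 with array weights, 72 at 2-fold, 216 without both B arrays, and 43 to 161 with arrays left out (67 without control 48 h A, 61 without plant 48 h C, 46 without control 120 h A, 57 without plant 120 h A, 43 without control 120 h B, 58 without plant 120 h C).

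The 4 lists at 48 h became 1 with an estimated correlation, 1 with fry, 7 without both B arrays, and 4 to 8 with arrays left out (8 without plant 48 h A). The 8 lists at 120 h became 0 with an estimated correlation (7 unadjusted; fry 11), and 7 to 11 with arrays left out.

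Replicate letters did not pair plant and control arrays: their deviations from group means correlated across genes at -0.25, -0.48 and 0.02 (A, B, C) at 48 h and -0.28, 0.10 and 0.26 at 120 h. Across time they correlated at 0.36, 0.11 and -0.14 without plants and 0.39, 0.33 and 0.03 with plants. Within a time 5 of 12 arrays correlated best with their own letter. With the letter as a replicate block the counts were 0 at 48 h (184 unadjusted in limma), 696 at 120 h, 717 and 58 over time and 101 for the difference, and with a block within each time 0 (179 unadjusted), 588 and 53, while the time comparisons cannot be estimated with it. The consensus correlation within letters was 0.0164. Lists called were 4 and 8 with the block.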

Other observations

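All values here were chosen only after results were seen, except the test of neighbouring genes, which was set before.

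Changed genes of the 120 h plant comparison lay side by side on the chromosome. Arginine deiminase stood in a run of 6 neighbours that rose, PP0998 to PP1003, with carbamate kinase, ornithine carbamoyltransferase and arginine/ornithine antiporters, the genes of arginine fermentation (median 1.63). The run PP3312 to PP3318 held 7 genes that fell (median -1.62), among them heat shock proteins and a chaperone-associated ATPase. Runs of 6 rose at PP5003 to PP5008 (polyhydroxyalkanoate, median 1.19), PP5415 to PP5420 (ATP synthase, 1.16) and PP3105 to PP3110 (1 rhs-related gene among hypothetical proteins, 0.82). The run PP4552 to PP4557 fell (median -1.32), with an R-specific enoyl-CoA hydratase, an ECF sigma factor and 4 hypothetical proteins. Runs of 5 rose at PP3376 to PP3380 (2-ketogluconate, 0.93), PP4863 to PP4867 (branched-chain amino acid transport, 0.93) and PP2684 to PP2688 (hypothetical proteins and a transglutaminase-like protein, 1.56), and a run of 5 fell at PP4855 to PP4859, with OsmE and a putative bacterioferritin (-0.57).

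Of the genes called at 120 h, 33.7% had a next gene called in the same direction, against a mean of 7.05% and a highest value of 11.02% in 1000 random draws of as many genes. This is consistent with genes of one transcription unit changing together, a hypothesis, since operons were not mapped here.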
